A study of Homo sapiens with 10 samples.

How the data were processed

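The deposited data are a table of read counts per gene for 10 libraries of total RNA from the human prostate cancer cell line PC3. Of these, 9 come from extracellular vesicles (EVs) pelleted at 3 centrifugation speeds, with 3 libraries per speed, and 1 comes from whole cells. Per the labels' protocols, the cells grew in DMEM with fetal bovine serum, RNA was extracted with Trizol, and libraries were made with a SMARTer stranded total RNA kit for low input, which also captures RNA without a poly(A) tail. Groups and set numbers were taken from the sample titles. The labels name the speeds as 2.8K, 10K and 100K, with no unit.

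Per the submitters' processing notes, the authors used bcl2fastq 2.19.1.403, cutadapt 2.7, STAR 2.6.1d and featureCounts 1.6.3 with the genome build GRCh38. The annotation, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. The deposited counts are whole numbers that were not normalized. The table has 94946 entries, of which 45574 carry gene identifiers of GENCODE release 29 and 49372 carry names of a long noncoding RNA catalogue. Symbols and coordinates were taken from GENCODE release 29 on GRCh38 by identifier, and positions of the catalogue entries were not used here. Since the counting of shared reads is not stated, counts of genes with near-identical copies (ribosomal protein genes and their pseudogenes, mitochondrial genes and their nuclear copies, clustered histone genes) and of overlapping or antisense genes are uncertain.

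Total counts ranged from 5424964 to 28735081 per library. A count of 0 allows up to 3 counts of the total, and intervals and floors cover counting error only, since the reads are not independent molecules. For a group with no count, levels are given and no fold change. CPM values (counts relative to a library total of 1e+06) were scaled by the TMM factors of all 10 libraries, and shares are percentages of all counts of a library.

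Differential tests used edgeR 4.0.16 in R 4.3.3: filterByExpr by group with a minimum count of 10, TMM normalization, and the quasi-likelihood F-test with robust estimation of the spread. The p-values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The 3 pairwise comparisons of pellets, and a joint test for any difference between them, were fitted on the 9 EV libraries without a term for the set number (15525 genes, 6 residual degrees of freedom, prior degrees of freedom 11.7). The comparisons with whole cells were fitted on all 10 libraries (22370 genes). The cell library has no replicate, and the prior degrees of freedom of this fit were estimated as infinite, so that all genes share 1 trend of spread.

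Before the data were examined, 31 gene lists with 1046 genes were fixed, covering RNA classes, pathways and EV cargo. They include blood and serum, leukocyte and fibroblast genes as markers of other sources, and olfactory receptor and neuronal genes as background. Lists were tested with camera of limma 3.58.1 (two-sided) with a preset correlation of 0.01 between genes and, beside it, an estimated one. These p-values were adjusted over all 110 tests of lists with at least 5 tested members in the 4 main comparisons. Counts of list members are given over all genes tested and adjusted over the list alone. Shares of 13 RNA classes and the number of genes detected were compared with exact two-sided permutation tests over all assignments of the 9 EV libraries to 3 groups. Detection was compared after thinning each library to the depth of the smallest one. Any 3 libraries against 3 cannot give an exact permutation p below 0.1, so classes were not compared pairwise. Single shares carry 95% Wilson intervals, computed with scipy 1.17.1 under Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

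The genes named in the text follow a rule fixed before the data were examined. It takes, for each main comparison, the 8 genes with the highest and the 8 with the lowest log2 fold change among those that passed, with a mean of at least 10 CPM in the higher group and the same sign in every same-numbered pair (or in all 9 EV libraries against the cells). Clone, LOC, LINC and pseudogene names were left out. It adds up to 3 members of each list with the smallest p among those that passed, and a set of genes fixed by name, such as CD9, CD63 and GAPDH. From these, the text gives a part, and results for some genes are not reported here. Members of counts of 5 or fewer outside the rule are named and marked as chosen after their values were seen.

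The scripts were tested on simulated counts with 200 changed genes, drawn from the means, the library sizes and 1 spread per gene of the real data. For EV 100K against EV 2.8K (15525 genes), 11 of 100 genes changed 2-fold and 47 of 100 changed 4-fold were recovered, with 10 unchanged genes called. For the mean EV against the cell library (22311 genes), 2 of 99 and 18 of 100 were recovered, with 1 unchanged gene called. Of 20 simulated lists of 40 genes shifted 2-fold, 20 were recovered, and 1 of 20 lists without a shift was called. The simulated genes were drawn independently, so this cannot show how often camera calls lists of correlated genes falsely.

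The alternatives were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, no filter and a stricter filter on low counts (at least 5 CPM in at least 3 libraries), a term for the set number, each EV library left out in turn, the fit without mitochondrially encoded and small noncoding RNA genes, estimation of the spread without robustness, fits on the 6 libraries compared or on all 10, an estimated correlation in camera, and other definitions of shares and detection. After seeing the data, fits and shares without the most abundant catalogue entry and fits on counts thinned to equal depth were added.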

Results

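The data are total RNA sequencing counts of extracellular vesicles (EVs) and cells of PC3, a human prostate cancer cell line derived from a bone metastasis. Vesicles were collected at 3 centrifugation speeds, which the labels give as 2.8K, 10K and 100K without a unit, and the pellets are called EV 2.8K, EV 10K and EV 100K here. Each pellet has 3 libraries, numbered as sets, and 1 library of whole PC3 cells serves as the reference. The EV 2.8K libraries held 14856424, 14977955 and 10288246 counts and the EV 10K libraries 9710041, 7933251 and 10864958. The EV 100K libraries held 8083438, 5424964 and 6631087 counts, and the cell library 28735081. Nothing in the sources used here says that the sets came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Libraries of 1 pellet had Spearman correlations across genes of 0.862 to 0.913 for EV 2.8K, 0.905 to 0.921 for EV 10K and 0.964 for each EV 100K pair. The biological coefficient of variation was 0.929 in EV 2.8K, 0.736 in EV 10K and 0.273 in EV 100K. All pairs of libraries differed by more than sampling noise, so none was treated as a duplicate.

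Mitochondrially encoded RNA fell steeply from the slowest to the fastest spin. It made up 7.53 ± 4.63% of counts in EV 2.8K (SD, n = 3; 12.9, 4.92 and 4.81% in the single libraries), 0.954 ± 0.114% in EV 10K and 0.00645 ± 0.00138% in EV 100K. The cell library held 2.88% (95% Wilson interval 2.87 to 2.88%, counting error only). The difference between the pellets had an adjusted p of 0.00774 in an exact two-sided permutation test over all assignments of the 9 EV libraries to the pellets, adjusted over 13 RNA classes. Entries of a long noncoding RNA catalogue rose with spin speed, at 4.54 ± 0.528, 8.44 ± 1.23 and 11.5 ± 1.81% of counts (exact permutation adjusted p = 0.0133), against 2.16% in the cell library. In EV 10K and EV 100K most of these counts fell on 1 entry, lnc-ARF6-1, which may hold reads of another abundant RNA, since coordinates of the catalogue were not used here. With this entry left out, a choice made after seeing the data, the others made up 1.94 ± 0.631, 1.92 ± 0.148 and 2.86 ± 0.203% of the counts left, against 2.004% in the cell library, and did not pass (exact permutation adjusted p = 0.106). Small nuclear, nucleolar and Cajal body RNAs took 0.0585 ± 0.0126, 0.0312 ± 0.00881 and 0.0177 ± 0.00204% of counts, and snoRNA host transcripts 0.0645 ± 0.0103, 0.0835 ± 0.00357 and 0.112 ± 0.0104% (exact permutation adjusted p = 0.00774 for each). The cell library held 0.0221% and 0.0715% of these classes. Single RNAs of the first kind went both ways. SNORA23 was at 164, 49.7 and 2.42 CPM and SCARNA21 at 147, 58.5 and 2.80 CPM in EV 2.8K, EV 10K and EV 100K. The small nuclear RNAs RNU6ATAC (6.48, 34.1 and 49.1 CPM) and RNU6-8 (7.26, 17.9 and 32.4 CPM) had rising means.

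Ribosomal protein mRNAs made up 4.94 ± 0.269% of counts in EV 2.8K, 6.32 ± 0.668% in EV 10K and 6.004 ± 0.401% in EV 100K (SD, n = 3), against 2.72% in the cell library. Their exact permutation adjusted p was 0.0361. It rose above the threshold when EV 2.8K replicate 1 (0.0789), 2 (0.0511) or 3 (0.102), EV 10K replicate 2 (0.0516) or EV 100K replicate 2 (0.0567) or 3 (0.0557) was left out, and to 0.129 for shares of the counts without mitochondrially encoded genes. Replication-dependent histone mRNAs, which lack a poly(A) tail, made up 0.269 ± 0.0266, 0.445 ± 0.0445 and 0.449 ± 0.0725%, against 0.790% in the cell library (exact permutation adjusted p = 0.0464). That call was lost without EV 2.8K replicate 1 (0.0567), 2 (0.0511) or 3 (0.0580) or EV 10K replicate 2 (0.0516), and without mitochondrially encoded genes (0.0643). Neither the ribosomal protein call nor the histone call held under permutation within set numbers. RNA polymerase III transcripts such as Y and vault RNAs made up 0.0118 ± 0.00178, 0.0370 ± 0.0329 and 0.0317 ± 0.00646% (0.0743, 0.0246 and 0.0121% in the single EV 10K libraries) and did not pass (exact permutation adjusted p = 0.193). They passed without EV 10K replicate 1 (0.0258) or 3 (0.0371). The RN7SL and RN7SK entries had 0 counts in all libraries, so these shares do not cover all RNA polymerase III transcripts. Nuclear long noncoding RNAs such as NEAT1 made up 0.517 ± 0.301, 0.191 ± 0.0252 and 0.285 ± 0.0665% and did not pass either (0.193), but did without EV 2.8K replicate 1 (0.00663). In all, 10 of the 13 classes passed.

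After thinning every library to 5424964 counts, 16382 ± 1865 genes had at least 1 count in EV 2.8K, 15982 ± 349 in EV 10K and 19171 ± 193 in EV 100K (SD, n = 3; exact permutation p = 0.0357), and 22361 in the cell library. EV 2.8K replicate 1, at 14242 genes, stood apart from replicates 2 and 3 (17662 and 17241), which lay above every EV 10K library (15748, 16383 and 15815). With a minimum of 5 counts the difference between the pellets did not pass (exact permutation p = 0.429).

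**Figure D1:**
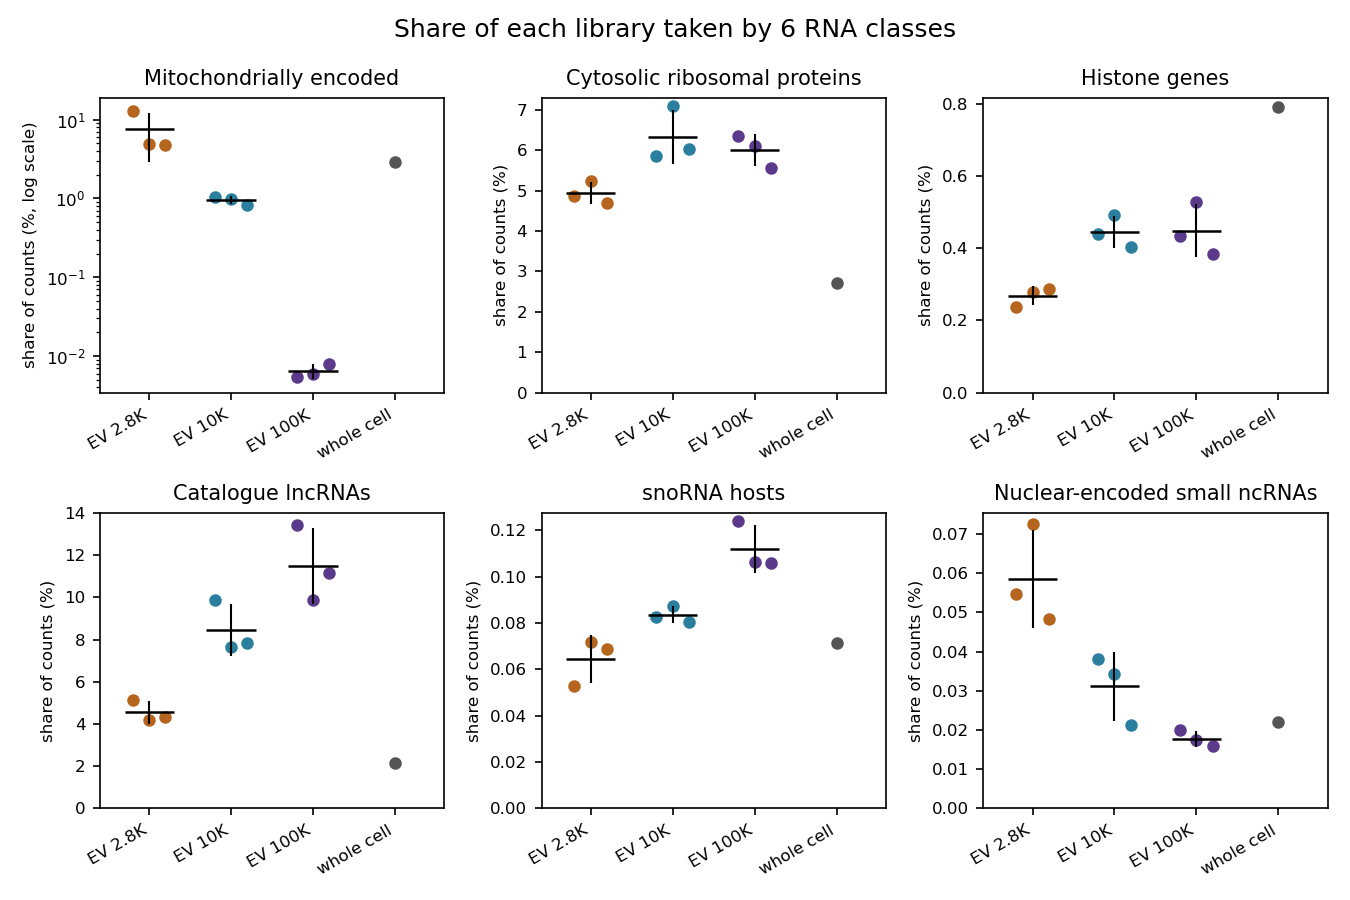
Share of all counts (percent, y axis; log scale for the mitochondrial panel) of 6 RNA classes in EV 2.8K, EV 10K, EV 100K and the cell library (x axis), where dots are libraries, horizontal bars means and vertical lines 1 SD. Mitochondrially encoded RNA falls from 7.53% in EV 2.8K to 0.00645% in EV 100K, while entries of the long noncoding RNA catalogue, most of whose counts in EV 10K and EV 100K lie on lnc-ARF6-1, rise from 4.54 to 11.5%.

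The first comparison between pellets asks how the RNA of vesicles collected at the 10K spin differs from that of the 2.8K spin. Part of the ribosomal protein and histone mRNAs rose in EV 10K, while mitochondrial mRNAs and part of the extracellular matrix and NF-κB target mRNAs fell. RPL37, a protein of the large ribosomal subunit (GRCh38 chromosome 5, 40825262 to 40835335), was at 59.8 ± 6.22 CPM in EV 2.8K and 452 ± 111 in EV 10K (SD, n = 3 each). Its log2 fold change was 2.90 (SE 0.24, edgeR adjusted p = 1.55e-06). RPL23 (1.88, SE 0.21) and RPS6 (1.45, SE 0.20) rose too. Of 79 ribosomal protein genes, 20 rose, 0 fell and 59 did not pass, and 24 rose when adjusted over the list alone. The list stood above other genes in camera (adjusted p = 7.9e-10), with adjusted p = 0.252 with an estimated correlation. Of 41 histone genes tested, 14 rose and 0 fell. Adjusted over the list alone, 24 rose and 0 fell (camera adjusted p = 1.91e-12, and 0.0395 with an estimated correlation). Among them H4C2, which encodes histone H4, went from 91.9 ± 37.4 to 518 ± 122.9 CPM (log2 2.48, SE 0.28) and H2AC12 rose by 1.81 (SE 0.24). The initiation factor EIF5B (1.77, SE 0.23), the splicing regulator RBM25 (1.77, SE 0.24), the small GTPase RAB40B (3.43, SE 0.31), the complex III subunit UQCRB (1.27, SE 0.20) and the proteasome ATPase PSMC6 (1.25, SE 0.21) rose as well.

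All 13 mitochondrial mRNAs fell from EV 2.8K to EV 10K, also when adjusted over the list alone (camera adjusted p = 8.08e-29, and adjusted p = 0.0501 with an estimated correlation). MT-CO1, a cytochrome c oxidase subunit, went from 12440 ± 8969 to 1592 ± 287 CPM (log2 -2.98, SE 0.38), and the ribosomal RNA MT-RNR1 changed by -2.91 (SE 0.39). Of 39 matrix and mesenchymal genes tested, 12 fell and 1 rose. Among the lower genes were the adhesive glycoprotein THBS1 (-1.94, SE 0.27) and the collagen VI chain COL6A1 (-1.39, SE 0.22). The counts were 26 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.91e-12, and 0.0395 with an estimated correlation). The gene that rose was ZEB1, a transcription factor of epithelial to mesenchymal transition (log2 1.70, SE 0.19, edgeR adjusted p = 2.49e-05). Of 20 NF-κB target genes tested, 5 fell and 0 rose (9 and 1 adjusted over the list alone; camera adjusted p = 1.71e-05, and 0.0395 with an estimated correlation). They were the feedback inhibitors TNFAIP3 (-2.92, SE 0.54) and NFKBIA (-1.81, SE 0.26), the chemokines CXCL1 (-2.26, SE 0.44) and CXCL2, and the adhesion molecule ICAM1. CXCL2 and ICAM1 were named after their values were seen. CXCL2 (edgeR adjusted p = 0.0334) lost the call without EV 2.8K replicate 2 or 3, any EV 10K library or EV 100K replicate 1 (0.0508 to 0.137). ICAM1 (0.0494) lost it without EV 2.8K replicate 2 or 3, EV 10K replicate 1 or 2, or EV 100K replicate 1 or 2 (0.0523 to 0.176), and in several other settings.

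Of 43 genes of the endoplasmic reticulum and secretory pathway, 10 fell from EV 2.8K to EV 10K and 2 rose (14 and 3 adjusted over the list alone; camera adjusted p = 9.34e-06, and adjusted p = 0.206 with an estimated correlation). The oligosaccharyltransferase subunit RPN2 (log2 -1.62, SE 0.23), the disulfide isomerase PDIA4 (-1.43, SE 0.22) and the chaperone HSP90B1 (-1.20, SE 0.19) fell. The 2 that rose, named after their values were seen, were the signal peptidase SEC11A (1.47, SE 0.30) and the signal recognition particle protein SRP9 (0.81, SE 0.23). SRP9 lost the call without EV 2.8K replicate 2 or 3, any EV 10K library or EV 100K replicate 2 (edgeR adjusted p = 0.058 to 0.119). The nuclear antisense transcript KCNQ1OT1 (-2.69, SE 0.38) fell. The spindle assembly factor TPX2 fell by 1.29 on the log2 scale (SE 0.23), and the snoRNA host SNHG16 rose by 1.16 (SE 0.20). GAPDH (0.08, SE 0.20) and ACTB (-0.57, SE 0.21) did not pass. Over all 15525 genes tested, edgeR called 990 at an adjusted p below 0.05, 645 higher and 345 lower in EV 10K, and 557 without EV 10K replicate 1. The lower genes numbered 174, 196 and 167 without EV 10K replicate 1, 2 and 3, 199 in a fit on the 6 libraries compared, 531 in a fit on all 10 and 638 with the DESeq2 Wald test. The main fit shared its spread with the EV 100K libraries, which varied less, so p-values of this comparison may be too small.

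The comparison of EV 100K with EV 2.8K, the fastest and the slowest spin, gave the most differences between pellets. The 13 mitochondrial mRNAs all fell, with a median log2 fold change of -9.98 (camera adjusted p = 1.76e-54, and 0.0395 with an estimated correlation), and the same count fell when adjusted over the list alone. MT-CO1 went from 12440 ± 8969 to 10.8 ± 2.78 CPM (SD, n = 3 each; log2 -10.18, SE 0.53, edgeR adjusted p = 1.54e-08). MT-ND6, a complex I subunit on the light strand, was at 364.4, 61.83 and 59.37 CPM in the EV 2.8K libraries and had no count in EV 100K. Cytoskeletal mRNAs fell in 30 of 40 genes and rose in 2. Adjusted over the list alone, 33 fell and 2 rose (camera adjusted p = 7.66e-19, and 0.0395 with an estimated correlation). ACTB (beta-actin) changed by -2.61 (SE 0.23) and the myosin light chain MYL12B by -2.82 (SE 0.23). The tubulins TUBA1B (0.78, SE 0.18) and TUBA1C (0.97, SE 0.18), named after their values were seen, rose. Of 18 glycolysis genes tested, 15 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 2.49e-11, and 0.0395 with an estimated correlation). The pyruvate kinase PKM was at -2.55 (SE 0.23), the triosephosphate isomerase TPI1 at -1.87 (SE 0.19) and GAPDH at -1.84 (SE 0.20). The gene that rose was the lactate dehydrogenase LDHA (0.48, SE 0.17; edgeR adjusted p = 0.0434), named after its value was seen, which lost the call without EV 2.8K replicate 1 or 3 or any EV 100K library (0.051 to 0.16).

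Genes of the secretory pathway and the matrix were also lower in EV 100K than in EV 2.8K. Of 43 secretory pathway genes, 30 fell and 2 rose (33 and 2 adjusted over the list alone; camera adjusted p = 6.55e-14, and adjusted p = 0.0656 with an estimated correlation). The chaperone CALR went from 2312 ± 503 to 286 ± 32.3 CPM (log2 -3.03, SE 0.22, edgeR adjusted p = 4.16e-08). HSP90B1 changed by -2.90 (SE 0.20) and SRP14 by -2.74 (SE 0.21). The signal peptidase genes SEC11A (1.93, SE 0.30) and SEC11C (1.26, SE 0.28), named after their values were seen, rose. Of 39 matrix and mesenchymal genes, 29 fell and 1 rose (31 and 1 adjusted over the list alone; camera adjusted p = 7.8e-16, and 0.0395 with an estimated correlation). THBS1 (-3.59, SE 0.30), COL6A1 (-2.94, SE 0.23) and TIMP1 (-2.98, SE 0.24) were among the lower genes, and the 1 higher gene was again ZEB1 (2.13, SE 0.20). Of 20 NF-κB targets, 11 fell, such as NFKBIA (-3.65, SE 0.28), and 2 rose. The 2 were LIF (2.53, SE 0.32) and SOD2 (1.46, SE 0.26; named after its value was seen). These counts were 12 and 2 adjusted over the list alone (camera adjusted p = 0.000234, and 0.0395 with an estimated correlation). Nuclear-encoded respiratory chain genes fell in 30 of 64 and rose in 7 (36 and 8 adjusted over the list alone; camera adjusted p = 1.94e-05, and 0.0395 with an estimated correlation), with NDUFB7 at -2.19 (SE 0.23) and COX6C at -1.82 (SE 0.19). Heat shock genes fell in 13 of 24, such as HSP90AB1 (-1.97, SE 0.19), and rose in 2, the chaperonin subunits CCT6A (1.36, SE 0.19) and TCP1 (0.79, SE 0.21), both named after their values were seen. Adjusted over the list alone, 13 fell and 3 rose (camera adjusted p = 1.22e-05, and 0.0395 with an estimated correlation).

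Ribosomal protein mRNAs did not move as 1 group between EV 2.8K and EV 100K. Of 79 genes, 20 rose and 15 fell (23 and 17 adjusted over the list alone), and the list did not pass in camera (limma adjusted p = 0.23). RPL37 rose from 59.8 ± 6.22 to 1064 ± 294 CPM (SD, n = 3 each; log2 4.13, SE 0.25), RPL23 by 2.81 (SE 0.22) and RPS6 by 2.30 (SE 0.21). Ribosomal protein genes have many processed pseudogene copies in the genome, and how reads shared with such copies were counted is not given in the sources used here, so their counts are uncertain. Of 41 histone genes, 15 rose and 2 fell (17 and 2 adjusted over the list alone; camera adjusted p = 0.000122, and adjusted p = 0.179 with an estimated correlation). H4C2 was at 913 ± 154 CPM in EV 100K (log2 3.29, SE 0.28). The 2 that fell, named after their values were seen, were H2BC12 (-1.05, SE 0.21) and H2AC6 (-0.96, SE 0.28). H2AC6 lost the call without EV 2.8K replicate 2 or 3 or EV 100K replicate 1 or 3 (edgeR adjusted p = 0.0619 to 0.103). Mitotic genes fell in 21 of 45, such as the kinesin KIF20A (-3.40, SE 0.28), and rose in 1, BIRC5 (1.16, SE 0.19; named after its value was seen). The counts were 25 and 1 adjusted over the list alone (camera adjusted p = 3.43e-08, and adjusted p = 0.0912 with an estimated correlation). The box H/ACA and Cajal body RNAs SNORA23 (-6.12, SE 0.45) and SCARNA21 (-5.72, SE 0.35) fell, while the noncoding RNAs NORAD (2.14, SE 0.24) and SNHG16 (2.10, SE 0.21) and the Y RNA gene RNY1 (3.35, SE 0.51) rose. In all, edgeR called 4013 of 15525 genes at an adjusted p below 0.05, 1865 higher and 2148 lower in EV 100K. In simulated counts for this comparison, 47 of 100 genes changed 4-fold and 11 of 100 changed 2-fold were called, along with 10 unchanged genes (14.7% of the calls). Only 200 genes were changed there, with the same spread in all pellets, so these shares do not give the power of the real test.

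**Figure D2:**
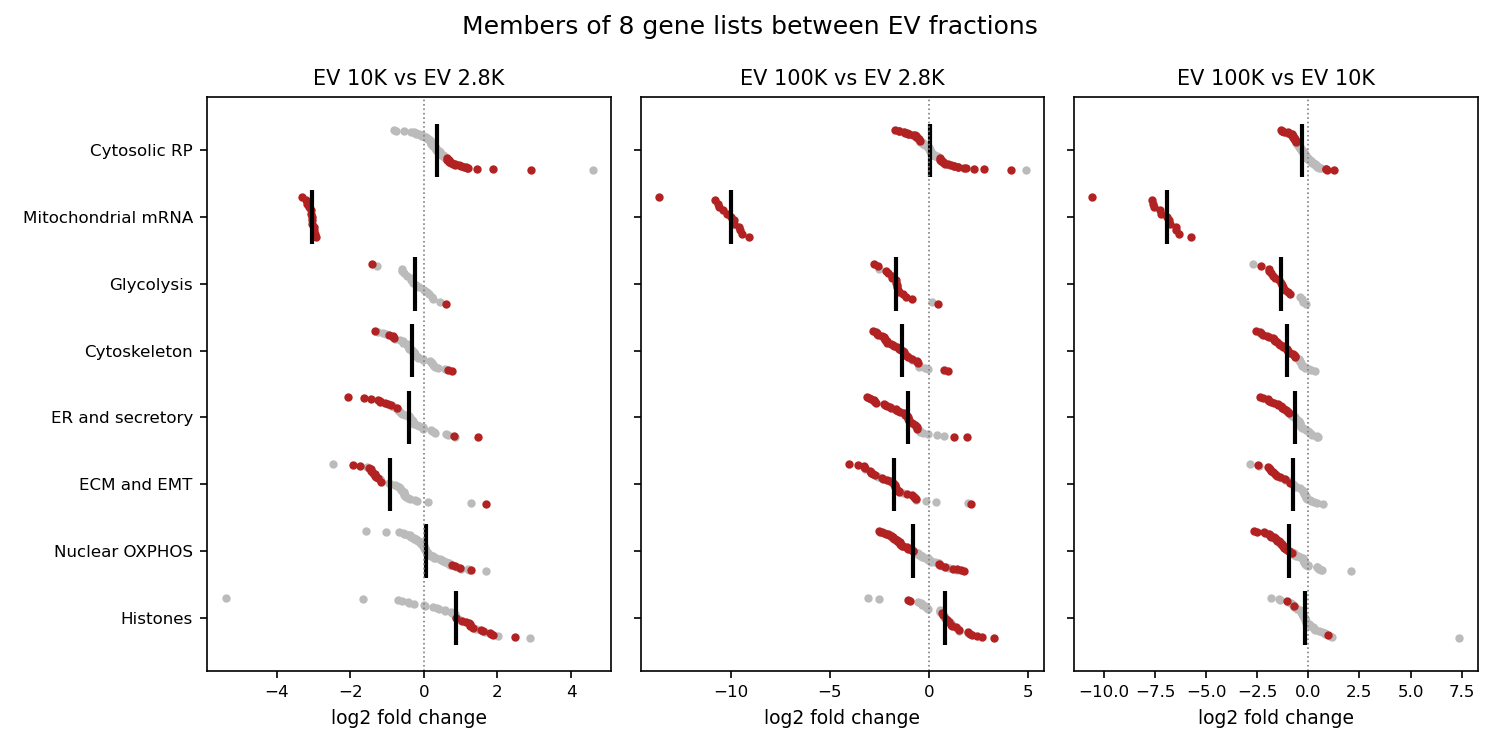
Log2 fold change (x axis) of each tested member of 8 gene lists (y axis) in the 3 comparisons between pellets (panels), with red points for genes at an edgeR adjusted p below 0.05, grey points for the others and a black bar at the median. All 13 mitochondrial mRNAs lie below 0 in each comparison, and ribosomal protein genes lie on both sides of 0 in EV 100K against EV 2.8K (20 rose and 15 fell).

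Between EV 100K and EV 10K most called genes were lower in EV 100K. The 13 mitochondrial mRNAs fell again, also adjusted over the list alone (camera adjusted p = 2.81e-78, and 0.0395 with an estimated correlation). MT-CO1 had a log2 fold change of -7.21 (SE 0.48, edgeR adjusted p = 1.42e-06; n = 3 each). Of 40 cytoskeletal genes, 23 fell and 0 rose (28 and 0 adjusted over the list alone; camera adjusted p = 3.75e-24, and 0.0395 with an estimated correlation). They included MYL12B (-2.55, SE 0.22), the actin-sequestering TMSB4X (-2.37, SE 0.24) and ACTB (-2.04, SE 0.22). Of 18 glycolysis genes, 13 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 1.4e-16, and 0.0395 with an estimated correlation), with GAPDH at -1.93 (SE 0.20) and ENO1 at -1.62 (SE 0.19). Respiratory chain genes fell in 29 of 64 and rose in 0 (38 and 3 adjusted over the list alone; camera adjusted p = 1.01e-14, and 0.0228 with an estimated correlation). NDUFB7 was at -1.64 (SE 0.22) and COX6C at -1.55 (SE 0.19). Of 31 proteasome genes, 15 fell, such as PSMD8 (-2.08, SE 0.24), and PSMC6 rose (0.96, SE 0.21; named after its value was seen). Adjusted over the list alone, 20 fell and 1 rose (camera adjusted p = 1.31e-10, and 0.0395 with an estimated correlation). Spliceosome genes fell in 23 of 40 and rose in 0 (26 and 2 adjusted over the list alone; camera adjusted p = 3.46e-10, and 0.0481 with an estimated correlation), with PRPF31 at -1.84 (SE 0.22).

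In the same comparison, 17 of 43 secretory pathway genes fell and 0 rose (20 and 0 adjusted over the list alone; camera adjusted p = 1.31e-12, and adjusted p = 0.0912 with an estimated correlation). SRP14 had a log2 fold change of -2.38 (SE 0.21) and CALR one of -1.97 (SE 0.21). Mitotic genes fell in 11 of 45 and rose in 0 (18 and 1 adjusted over the list alone; camera adjusted p = 1.31e-10, and adjusted p = 0.0541 with an estimated correlation). The scaffold protein ANLN, which acts in the contractile ring, went from 2882 ± 1309 to 233 ± 43.3 CPM (SD, n = 3 each; log2 -3.64, SE 0.32), and the centromere kinesin CENPE fell by 2.85 (SE 0.28). Ribosomal protein genes fell in 20 of 79 and rose in 4 (26 and 6 adjusted over the list alone; camera adjusted p = 0.000333, and adjusted p = 0.478 with an estimated correlation). RPL23A was at -1.36 (SE 0.20) and RPLP2 at -1.30 (SE 0.20). The 4 that rose, named after their values were seen, were RPL37 (1.23, SE 0.23), RPL23 (0.93, SE 0.20), RPS27A (0.88, SE 0.22) and RPS6 (0.85, SE 0.20). RPL23 (edgeR adjusted p = 0.0524) and RPS6 (0.0737) lost the call without EV 10K replicate 3, and RPS27A without EV 10K replicate 2 (0.0597) or 3 (0.107) or EV 100K replicate 1 (0.0837). The cytokine LIF (1.50, SE 0.31), the receptor phosphatase PTPRJ (2.27, SE 0.41) and the sugar transporter SLC45A4 (2.14, SE 0.43) rose. In all, edgeR called 1697 of 15525 genes at an adjusted p below 0.05, 575 higher and 1122 lower in EV 100K. The count was 2549 without EV 2.8K replicate 1, which enters through the filter (16745 genes tested without it), the normalization and the shared spread. It was 1033 without EV 10K replicate 3, 979 without EV 100K replicate 1 and 1017 without EV 100K replicate 3. The higher genes numbered from 266 without EV 10K replicate 3 to 1055 without EV 2.8K replicate 1, 923 with the DESeq2 Wald test and 1199 in a fit on the 6 libraries compared. The lower genes outnumbered them in each of these.

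A joint test asks which genes differ between any of the 3 pellets, and edgeR called 3623 of 15525 genes. Of the 110 list tests over the 3 comparisons of pellets and the mean EV against the cell library, 66 passed in camera with the preset correlation (11 up, 55 down). With an estimated one, 22 passed (3 up, 19 down), so most lists that passed moved down. Other splits of the same 6 libraries gave up to 10, 18 and 19 list calls, against 14 for EV 10K against EV 2.8K, 19 for EV 100K against EV 2.8K and 18 for EV 100K against EV 10K. Each other split mixes the pellets unevenly, so part of the real difference stays in it. These counts therefore cannot show how strict the camera p-values with the preset correlation are.

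The comparison with the cell library asks which RNAs of the cells are over- or underrepresented in the vesicles. It rests on 1 cell library, whose spread was assumed to be that of the EVs, and the fit gave all genes of 1 expression level the same spread, so p-values of genes that vary between EV libraries are too small. RAB13, a small GTPase gene (GRCh38 chromosome 1, 153981617 to 153986358), was at 12.9 CPM in the cells and at 666 ± 86.8, 3017 ± 469 and 1382 ± 266 CPM in EV 2.8K, EV 10K and EV 100K (SD, n = 3 each). Its mean EV log2 fold change was 6.77 (SE 0.44). RASSF3, a Ras association domain gene (6.06, SE 0.41), and the immunoglobulin A inducing protein gene IGIP (6.55, SE 0.56) were also higher. CHD9NB and NTN5 had no count in the cell library and were at 19.3 ± 24.7, 17.4 ± 5.15 and 35.6 ± 11.9 CPM and at 4.35 ± 4.95, 20.8 ± 10.1 and 34.5 ± 17.2 CPM in the 3 pellets. Ribosomal protein mRNAs rose in 47 of 79 genes and fell in 0 (65 and 0 adjusted over the list alone; camera adjusted p = 1.57e-56, and 0.0395 with an estimated correlation). RPL37 was at 3.51 (SE 0.38), RPL23 at 2.58 (SE 0.33) and RPS6 at 2.50 (SE 0.32). Taken pellet by pellet, 30 of the 79 rose in EV 2.8K, 57 in EV 10K and 38 in EV 100K (58, 71 and 51 adjusted over the list alone). ZEB1 (3.54, SE 0.37), EIF5B (2.66, SE 0.34), the centromere protein CENPF (2.25, SE 0.33), ANLN (2.22, SE 0.33), the minor spliceosomal RNA RNU6ATAC (5.65, SE 0.89) and the desmosomal protein DSP (1.37, SE 0.31) were higher as well. Taken pellet by pellet, ANLN did not pass in EV 100K (0.19, edgeR adjusted p = 0.968) and DSP did not in EV 2.8K (0.69, 0.403).

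Part of the matrix and histone mRNAs were lower in the vesicles than in the cell library. COL6A1, the collagen VI chain (GRCh38 chromosome 21, 45981737 to 46005050), was at 1849 CPM in the cells and at 1015 ± 341, 390 ± 37.01 and 134 ± 15.6 CPM in the 3 pellets (SD, n = 3 each), with a mean EV log2 fold change of -2.30 (SE 0.23). Of 41 matrix and mesenchymal genes, 20 fell and 1, ZEB1, rose (23 and 1 adjusted over the list alone; camera adjusted p = 2.1e-09, and 0.0481 with an estimated correlation). COL6A1 is among them, and so is the fibronectin gene FN1 (-1.95, SE 0.27). Of 46 histone genes, 15 fell and 1 rose (23 and 1 adjusted over the list alone; camera adjusted p = 9.53e-07, and adjusted p = 0.0593 with an estimated correlation). The linker histone genes H1-3 and H1-2 were at -1.68 (SE 0.28) and -1.40 (SE 0.25). The 1 that rose was H4C2 (1.69, SE 0.33), named after its value was seen. Of 43 secretory pathway genes, 13 fell, such as PDIA4 (-1.44, SE 0.27), and 1 rose, SEC11C (1.34, SE 0.39; named after its value was seen; edgeR adjusted p = 0.0163, and 0.056 under a stricter filter on low counts). Adjusted over the list alone, 16 fell and 1 rose (camera adjusted p = 0.000243, and adjusted p = 0.296 with an estimated correlation). By pellet, 0 of the 43 fell in EV 2.8K, 8 in EV 10K and 27 in EV 100K, against 3, 19 and 28 of the 41 matrix genes and 24, 3 and 11 of the 46 histone genes. PDIA4 was at -0.05 (SE 0.33) in EV 2.8K. The integrin ITGA3 (-2.03, SE 0.24), the transglutaminase TGM2 (-2.63, SE 0.30), filamin FLNA (-1.77, SE 0.23), vinculin VCL (-1.52, SE 0.25), the replication clamp PCNA (-2.08, SE 0.32), ACTB (-1.41, SE 0.23) and LINC-PINT (-2.69, SE 0.26) were lower in the mean EV. In EV 2.8K alone, COL6A1, ITGA3, FLNA, VCL, ACTB and LINC-PINT did not pass (edgeR adjusted p = 0.064 to 0.79). GAPDH (-0.15, SE 0.26) and EEF1A1 (0.25, SE 0.27) did not pass in the mean EV. By pellet, GAPDH lay on both sides of the cell library, at 2316 ± 100, 2472 ± 409 and 653 ± 142 CPM against 1724 CPM.

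Relative to the cell library, mitochondrial mRNAs differed in direction between the pellets. Of the 13, 11 rose and 0 fell in EV 2.8K, and 0 rose and 13 fell in both EV 10K and EV 100K (12, 13 and 13 adjusted over the list alone). Their share of counts was 7.82% in EV 2.8K replicate 1 but 3.09 and 2.73% in replicates 2 and 3, against 2.27% in the cell library. The list had camera p = 2.41e-05, 2.56e-06 and 4.33e-21 with the preset correlation and p = 0.221, 0.18 and 0.0265 with an estimated one, not adjusted over lists. MT-CO1 was at 4451 CPM in the cells, with log2 fold changes of 1.48 (SE 0.31), -1.49 (SE 0.26) and -8.68 (SE 0.30) for EV 2.8K, EV 10K and EV 100K. Its calls in EV 2.8K and EV 10K were lost in several fits, as without EV 2.8K replicate 2 (edgeR adjusted p = 0.412 and 0.275) or any EV 10K library (0.573 to 0.683), and in EV 2.8K also without EV 2.8K replicate 1 (0.0898). Both were also lost without EV 100K replicate 1 (0.784 and 0.626) or 2 (0.348 and 0.117), and that in EV 2.8K without EV 100K replicate 3 (0.068). Cholesterol synthesis genes rose in 5 of 23, also adjusted over the list alone, and fell in 0 (camera adjusted p = 0.00235, and adjusted p = 0.389 with an estimated correlation). They include INSIG1 (2.40, SE 0.49), HMGCS1 (1.32, SE 0.39), IDI1 and PMVK, of which IDI1 and PMVK were named after their values were seen. HMGCS1 lost the call under a stricter filter on low counts (edgeR adjusted p = 0.0586). IDI1 lost the call without any 1 EV library except EV 2.8K replicate 1 (0.0683 to 0.189), and PMVK without any except EV 2.8K replicate 1 and EV 100K replicate 1 (0.065 to 0.624).

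Over all 22370 genes tested with the cell library, edgeR called 992 for the mean EV, 572 higher and 420 lower, and 1529 without EV 2.8K replicate 1. By pellet, 499 were called in EV 2.8K (344 higher, 155 lower), 990 in EV 10K (631 and 359) and 2247 in EV 100K (1026 and 1221). These were 752 for EV 2.8K without EV 2.8K replicate 3 (442 higher, 310 lower) and 1522 for EV 10K without EV 2.8K replicate 1 (900 and 622). The lower genes in EV 2.8K numbered 253 without EV 2.8K replicate 1 and 240 with the set number as a block. The balance of directions depended on the scaling. DESeq2 size factors moved the median log2 fold change of all genes by 0.118 for the mean EV, 0.113 for EV 2.8K and 0.150 for EV 100K, and gave 663 higher and 302 lower for the mean EV and 1177 and 968 for EV 100K. The DESeq2 Wald test gave 890 and 256 for the mean EV, 529 and 117 for EV 2.8K, 879 and 263 for EV 10K, and 1420 and 951 for EV 100K.

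**Figure D3:**
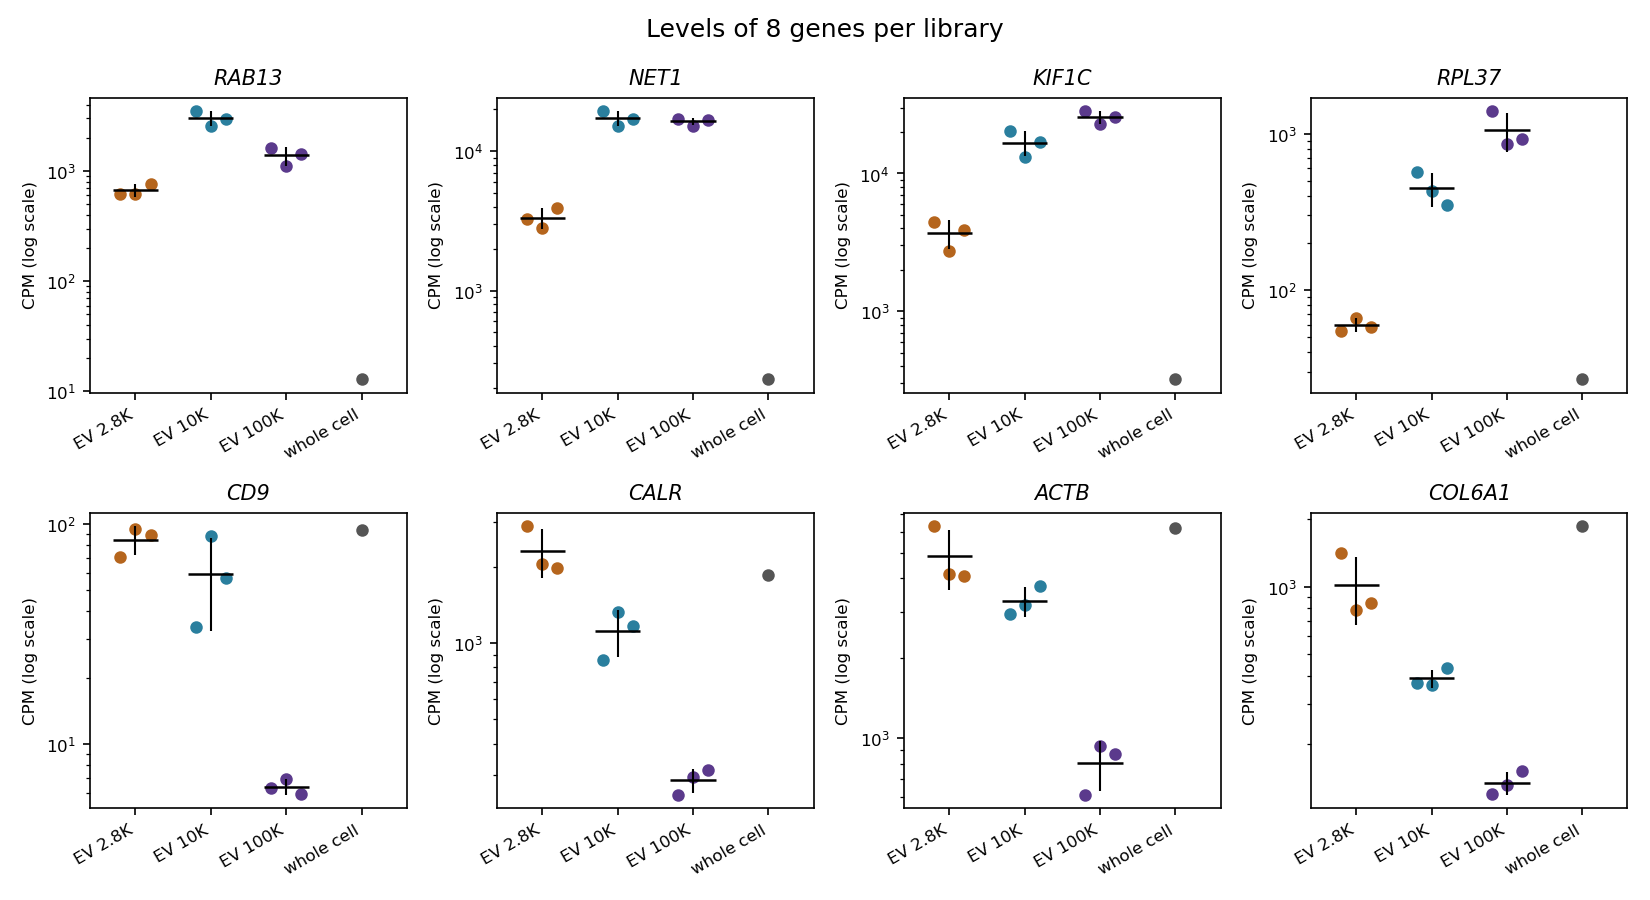
CPM (log scale, y axis) of RAB13, NET1, KIF1C, RPL37, CD9, CALR, ACTB and COL6A1 in EV 2.8K, EV 10K, EV 100K and the cell library (x axis), with dots for libraries, horizontal bars for means and vertical lines for 1 SD. RAB13 is at 12.9 CPM in the cells and at 666 to 3017 CPM in the pellet means, whereas CD9 falls from 84.7 CPM in EV 2.8K to 6.41 CPM in EV 100K.

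Many genes whose proteins serve as EV markers were lower in EV 100K than in the slower pellets. CD9 was at 84.7 ± 12.7 CPM in EV 2.8K, 59.5 ± 26.9 in EV 10K and 6.41 ± 0.527 in EV 100K (SD, n = 3 each), and at 93.4 CPM in the cell library. It fell from EV 2.8K to EV 100K (log2 -3.74, SE 0.37, edgeR adjusted p = 8.03e-07) and from EV 10K to EV 100K (-3.22, SE 0.36), and did not pass between EV 2.8K and EV 10K (-0.53, SE 0.32). CD63 was at 206 ± 45.3, 249 ± 54.0 and 301 ± 21.5 CPM, against 164 CPM in the cells, and did not pass in these comparisons (0.26, 0.53 and 0.26 between pellets). For EV 100K against EV 2.8K it did pass without EV 2.8K replicate 3 (edgeR adjusted p = 0.0437), with the set number as a block (edgeR adjusted p = 0.0404) and with DESeq2 (adjusted p = 0.0347). TSG101 averaged 17.04, 19.1 and 14.9 CPM and did not pass. Of 39 EV marker genes tested, 23 fell from EV 2.8K to EV 100K and 2 rose (24 and 3 adjusted over the list alone; camera adjusted p = 9.84e-11, and 0.0403 with an estimated correlation). From EV 10K to EV 100K, 18 fell, such as CD151 (-1.92, SE 0.24), and 2 rose (23 and 2 adjusted over the list alone; camera adjusted p = 2.19e-12, and 0.0395 with an estimated correlation). In both comparisons the 2 that rose, named after their values were seen, were the secretion GTPase RAB27A (2.57, SE 0.42, and 1.57, SE 0.40) and the ESCRT-I subunit VPS37B (2.67, SE 0.29, and 1.37, SE 0.28). From EV 10K to EV 100K, RAB27A lost the call without EV 10K replicate 3 (edgeR adjusted p = 0.0806) or EV 100K replicate 1 (0.115) or 2 (0.0682).

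Few markers of other cell types, and few genes not expected in PC3 cells, had enough counts for a test. Between pellets, the genes tested were 2 of 29 blood and serum genes, 2 of 26 leukocyte genes, 5 of 20 fibroblast genes, 0 of 79 olfactory receptor genes and 6 of 40 neuronal genes. The fibroblast gene FBLN1 fell from EV 2.8K to EV 100K (35.1 ± 14.2 to 11.6 ± 0.741 CPM) and no other gene of these lists passed. Against the cell library 9, 9, 9, 3 and 16 of them were tested, and the fibroblast gene COL6A3, at 315 CPM in the PC3 cells themselves, fell in the mean EV (log2 -1.92, SE 0.29) while no other passed. The bovine serum in the culture medium can carry bovine RNA, and reads from it were not analysed here.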

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

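The counts of genes called against the cell library rest on 1 cell library, and those between pellets on 3 libraries each, so they move with single libraries. Fits without the most abundant catalogue entry and on counts thinned to equal depth were chosen after seeing the data, and they kept every count of called genes within 1.5 times. Thinned counts gave 1021, 4113 and 1806 called genes for EV 10K against EV 2.8K, EV 100K against EV 2.8K and EV 100K against EV 10K, so depth was not seen to limit these, and 874 for the mean EV against the cell library (992 before). In simulated counts with 200 changed genes, 11 of 100 genes changed 2-fold and 47 of 100 changed 4-fold were called in EV 100K against EV 2.8K, and 2 of 99 and 18 of 100 for the mean EV against the cell library. The real comparisons called more genes, which loosens the adjusted threshold, so the share of real changes that was missed is not known.

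With an estimated correlation, 22 list tests passed against 66, and the cause was not tested. A stricter filter gave 285 called genes for EV 2.8K against the cell library (499 before). Fits on only the 6 libraries compared gave 561 for EV 10K against EV 2.8K (990 before) and 2777 for EV 100K against EV 10K (1697 before), and the DESeq2 Wald test gave 1635 for EV 10K against EV 2.8K. The fits on all 9 EV libraries share 1 spread per gene over pellets with biological coefficients of variation of 0.929 (EV 2.8K), 0.736 (EV 10K) and 0.273 (EV 100K). For the fit on all 9 libraries it was 0.695, below the values of EV 2.8K and EV 10K. The p-values for EV 10K against EV 2.8K may therefore be too small. Whether the shared spread or another cause moved these counts was not tested. Without mitochondrially encoded genes, 4 of 9 RNA classes passed against 10 of 13, where 4 classes drop out by construction. For genes detected with at least 5 counts the exact permutation p was 0.429, against 0.0357 with at least 1, and the cause was not tested.

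With single EV libraries left out, the counts ranged from 557 to 1173 for EV 10K against EV 2.8K, 979 to 2549 for EV 100K against EV 10K, 2807 to 4137 for EV 100K against EV 2.8K and 2478 to 4111 for any difference. Against the cell library they ranged from 826 to 1529 for the mean EV, 357 to 752 for EV 2.8K, 775 to 1522 for EV 10K and 1710 to 2974 for EV 100K. List calls ranged from 64 to 70 and classes from 7 to 11. Some genes changed sign in comparisons where they passed in no fit. TSG101 ranged from -0.43 to 0.83 (log2) in EV 10K against EV 2.8K, -0.79 to 0.47 in EV 100K against EV 2.8K and -0.69 to 0.12 in EV 100K against EV 10K. PDCD6IP ranged from -0.39 to 0.084 in EV 10K against EV 2.8K and EEF1A1 from -0.17 to 0.001 in EV 100K against EV 2.8K. The cause was not tested.

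With the set number as a block, the counts were 1075, 3964 and 1875 for EV 10K against EV 2.8K, EV 100K against EV 2.8K and EV 100K against EV 10K, with 67 list calls and 8 classes. Ribosomal protein (0.120) and histone mRNAs (0.144) did not pass there in the exact permutation test, CD63 passed in EV 100K against EV 2.8K (edgeR adjusted p = 0.0404), and TSG101 was at 0.48 in EV 100K against EV 2.8K. Deviations from the pellet mean correlated at -0.009 to 0.048 between libraries of the same number and at -0.036 to 0.03 between others. The means were 0.027 for the same number and -0.013 for others. Between EV 2.8K and EV 10K, and between EV 10K and EV 100K, each library correlated best with its own number. EV 2.8K replicate 3 did so in EV 100K too, while replicates 1 and 2 correlated best with another number there. All these correlations were small, so whether the sets pair the libraries stays open, and the main fits leave the numbers out.

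Of 5110 values for 265 results on named genes, 4853 kept direction and side of the threshold, 237 no longer passed, 12 newly passed and 8 changed sign. Of 792 values for 66 list results, 731 kept the call and 61 lost it, 44 of these with an estimated correlation. Of 152 values for 13 RNA classes, 126 kept their side, 21 no longer passed and 5 newly passed.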

Other observations

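KIF1C, a kinesin motor (GRCh38 chromosome 17, 4997948 to 5028401), took 0.380, 1.603 and 2.39% of counts in EV 2.8K, EV 10K and EV 100K, against 0.0389% in the cell library (log2 5.18 for the mean EV, SE 0.38). NET1, a RhoA exchange factor (chromosome 10, 5412551 to 5458463), took 0.349, 1.66 and 1.54% against 0.0279% (log2 5.41, SE 0.39). TRAK2, a kinesin adaptor, took 0.166, 0.755 and 0.796% against 0.00924% (log2 5.96, SE 0.41). These genes and those of the next paragraph were chosen after their values were seen.

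CIT, the citron kinase of the midbody, was highest in the middle pellet, at 1964 ± 805, 4721 ± 2107 and 492 ± 44.0 CPM (SD, n = 3 each) against 143 CPM in the cell library, and fell from EV 10K to EV 100K (log2 -3.27, SE 0.32, edgeR adjusted p = 9.7e-06). ANLN had the same order, at 1277 ± 437, 2882 ± 1309 and 233 ± 43.3 CPM. Of 13 genes of cytokinesis looked at, 5 had their highest mean in EV 10K (CIT, ANLN, INCENP, KIF23 and SEPTIN9), 7 in EV 2.8K, such as KIF20A (201, 108 and 19.3 CPM), and 1, RACGAP1, in EV 100K. Between EV 2.8K and EV 10K, ANLN lost the call without EV 2.8K replicate 2 (edgeR adjusted p = 0.0722) or 3 (0.0589) or EV 10K replicate 1 (0.146), and INCENP (0.247), KIF23 (0.998) and SEPTIN9 (0.787) did not pass. Of the 7, KIF20A passed there (0.036), while KIF14, ECT2, PRC1, CEP55, AURKB and KIF4A did not (0.107 to 0.96). RACGAP1 did not pass between any pellets (0.168 to 0.691). A noncoding entry, lnc-ARF6-1, took 3.97, 2.02 and 1.95% of counts in the EV 2.8K libraries, 7.94, 5.89 and 6.12% in EV 10K and 10.7, 7.41 and 8.52% in EV 100K, against 0.161% in the cell library. It ranked 1st in every EV library except EV 2.8K replicate 1, where it ranked 2nd, and 38th in the cell library. The RN7SL and RN7SK entries had 0 counts in all libraries. Coordinates of the catalogue were not used here, so whether reads of another abundant RNA were counted under lnc-ARF6-1 is open.

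All tests below were chosen after the patterns they concern were seen. Only for the 2 tests of transcript length and GC content was the outcome predicted beforehand. Of these, the test of KIF1C, NET1, TRAK2 and RAB13 concerned genes chosen for their values.

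Mitochondrial mRNAs were lower in EV 100K than in EV 2.8K. On counts thinned to equal depth, the median log2 fold change of the 13 mRNAs was -9.94 (95% bootstrap range over the mRNAs, not the libraries, -10.50 to -9.44). Thinning keeps the expected ratio between libraries, so the value could hardly move and does not decide on depth. Whole-cell material in the 2.8K pellet could carry mitochondrial RNA. The share of all mitochondrially encoded RNA in the EV 2.8K libraries was 1.67 to 4.47 times that of the cell library. The mRNAs alone made up 7.82, 3.09 and 2.73% of counts there, against 2.27% in the cell library. Since the cell side is 1 library, whole-cell material stays open as an explanation. That vesicles of different size enclose mitochondrial RNA to a different extent is a hypothesis that was not tested.

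Cytoskeletal and glycolytic mRNAs were lower in EV 100K than in EV 2.8K, with a median log2 fold change of -1.54 for 58 members (95% bootstrap range over members, not libraries, -1.82 to -1.25), against -0.12 for all 11996 nuclear protein-coding genes tested with a known length. Fold changes rose with transcript length (Spearman 0.25) and fell with GC content (Spearman -0.191). After removal of both trends the median was -1.32 (-1.58 to -1.19), which argues against length and GC content as the whole cause. On thinned counts, with both trends left in, the median was -1.51 (-1.81 to -1.25). Thinning could hardly move this value, so it does not decide on depth. That the pellets hold vesicles with different mRNA content stays open as untested.

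KIF1C, NET1, TRAK2 and RAB13 were higher in the EVs than in the cell library. Of 200 protein-coding genes matched to each for length, GC content and level, 5, 3, 1 and 0 had a log2 fold change as high, but the 4 genes were chosen for their values and the cell side is 1 library, so length and GC content stay open. All 4 mRNAs are known to localise to cell protrusions, and the hypothesis that this class as a whole is enriched in EVs was tested on 5 other members. For the mean EV only 1, PKP4, passed as higher (log2 1.99, SE 0.34), while DYNLL1 (0.02, SE 0.32), CYB5R3 (-0.90, SE 0.32), DDR2 (2.71, SE 1.86) and KANK2 (0.81, SE 0.31) did not pass. In EV 100K alone, PKP4 (2.29, edgeR adjusted p = 2.41e-08) and KANK2 (1.30, 0.00258) were higher and CYB5R3 (-2.42, 6.88e-10) and DYNLL1 (-0.96, 0.0387) were lower than in the cell library. With 1 cell library the hypothesis stays open.

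Other splits of the libraries were tested too. For EV 10K against EV 2.8K, EV 100K against EV 2.8K and EV 100K against EV 10K, the real splits gave 990, 4013 and 1697 genes and the highest other split 0 each, so 1 of 10 splits reached the real count. For list calls the real splits gave 14, 19 and 18 and the highest other 10, 18 and 19, so 1, 1 and 2 of 10 splits reached the real count. With 10 splits, there are too few for a share under 0.05. For any difference between the 3 pellets, only the real split of 100 drawn from 280 reached 3623 genes, and the highest other gave 1671. This argues against a chance assignment of these libraries to pellets. It does not show that the difference recurs in other cultures, since the sets may be technical replicates.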
